A study of Dendrobium huoshanense with 6 samples.

How the data were processed

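RNA sequencing of 6 libraries from whole seedlings of Dendrobium huoshanense was used, 3 from normal growth and 3 from cold, grouped by the treatment label of each sample. Per the labels' protocols, messenger RNA was enriched with oligo(dT) beads, fragmented and copied into cDNA with random hexamers. The protocol text is the same for every sample, names 4 °C and speaks of both cold and freezing stress; the temperature of the normal growth group is not given in the sources used here. The submitters' processing notes name Bowtie2 2.2.5, RSEM 1.2.8 and DESeq2, with no role for each. The assembler, the trimming and the way contigs were clustered are not given in the sources used here.

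Per the file headers, each library has 1 table with, for each contig, a length, an effective length, an expected count, TPM and FPKM. The expected counts deposited by the authors are RSEM estimates, in which a read that matches several contigs is divided between them, and 36.1% to 42.0% of all 181669 values in a library, zeros included, are not exactly whole as written. The TPM values deposited by the authors have the same sum in each library within rounding, and the FPKM values deposited by the authors are scaled to contig length and mapped reads. Gene and transcript IDs are identical in every row, so the tables hold 1 level. The contigs run from 200 to 29132 bases with a median of 764. A contig of an assembly can be a fragment, an allele or a splice form of a gene, so numbers of contigs are not numbers of genes, and reads shared between contigs of 1 cluster make the value of each uncertain. Clusters were taken here from the shared ID prefix (CL and a number), a reading of the IDs that the sources used here do not state.

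The tables identify contigs by ID and do not pair them with gene or product names, and contig sequences and an annotation were not used here. The 40 gene lists fixed before the data were examined, and the enrichment of functional terms, could therefore not be scored, and by the rule fixed for that case at most 2 contigs that rose and 2 that fell are named. The rule takes the largest log2 fold changes in each direction among contigs with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the groups. The main test and most alternatives were also fixed before the data were examined. The tests of clusters as a result of their own, of detection, of read concentration and of contigs seen in 1 group were chosen after seeing the data.

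Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Contigs were kept by filterByExpr at its defaults (about 10 reads in as many libraries as the smaller group holds, and 15 reads in total), which left 70729 contigs and 35987 clusters and unclustered contigs. Library sizes were scaled by TMM. Dispersions were fitted robustly, cold was compared with normal growth by the quasi-likelihood F test with no other term, and p-values were adjusted by Benjamini-Hochberg. The fold changes are cold over normal growth. The SE of a log2 fold change was taken as its size divided by the square root of F. Fitted folds of features with no read in a group depend on the prior count, so for these a lower bound was computed against 3 reads over the whole group. Libraries were compared by Pearson correlation and principal components of log2 CPM with a prior count of 2. For detection, each library was thinned at random to 15284111 reads.

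Depth ranged from 15284397 to 18085164 estimated reads per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The labels call the libraries biological repeats and do not say how many seedlings each held. No sequencing batch is given in the labels.

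The edgeR fit was tested on simulated data drawn from the real means, library sizes and dispersions for the comparison of cold with normal growth. Sets of 200 changed features were drawn from those with a mean of at least 2 CPM, and larger sets from all features kept by the filter. Counts were drawn independently for each feature, so reads shared between contigs were not simulated. With 200 contigs changed, 0% were recovered at 4-fold, 19.5% at 16-fold and 58.0% at 64-fold, with 65177 to 65438 contigs tested. The 64-fold cases and those with more changed contigs were added after the first simulation had recovered none of 200 contigs at 4-fold. With 14146 contigs changed 16-fold, 76.6% were recovered and 3.07% of the calls were false (64912 contigs tested). With 200 clusters changed, 19.0% were recovered at 4-fold, 71.5% at 16-fold and 88.5% at 64-fold, and 13.6%, 8.33% and 6.84% of the calls were false (33576 to 33942 tested). With 7198 clusters changed 16-fold, 87.4% were recovered and 3.08% of the calls were false (33708 tested). Median fitted log2 fold changes of the changed contigs were 1.94, 3.99 and 6.08 for true values of 2, 4 and 6.

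The alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom with limma 3.58.1, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1) for contigs with a mean FPKM of at least 0.5, counts summed per cluster (planned for the contig counts), an adjusted p under 0.01, and counts not rounded. All other divisions of the libraries into 3 and 3 were tested in the same way.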

Results

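Poly(A)-selected RNA was sequenced from whole seedlings of Dendrobium huoshanense, a medicinal orchid, kept under normal growth conditions or exposed to cold at 4 °C. Each group held 3 libraries, which the labels call biological repeats. The protocol names collection at 0 and 7 days, read here as day 0 for normal growth and day 7 for cold, and a light period of 11 h per day. On this reading the groups differ both in cold exposure and by 7 days of time and age, and all differences given below are between groups that differ in both. The values were estimated read counts for 181669 contigs of a transcript assembly shared by all libraries. Of these, 79016 carried a cluster prefix and fell into 16105 clusters, with a median of 3 contigs per cluster, and 102653 were unclustered. Contigs were identified by ID alone, so changes are described by contig and cluster and not by gene function. Estimated reads summed to 17683567, 18085164 and 17734859 in normal growth replicates 1, 2 and 3, and to 15284397, 16861750 and 17255112 in cold replicates 1, 2 and 3.

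The first comparison asked how far the transcript profiles of cold-exposed seedlings stood from those of seedlings in normal growth. The groups separated along the first principal component of the log2 CPM (counts scaled to library size), which held 54.0% of the variance over 70729 contigs. Pearson correlations of log2 CPM across contigs ranged from 0.77 to 0.86 between normal growth libraries, from 0.70 to 0.78 between cold libraries and from 0.43 to 0.57 between libraries of different groups. When the counts of the contigs of each cluster were summed, the same ranges were 0.89 to 0.93, 0.85 to 0.90 and 0.67 to 0.76, and the first component held 61.4% of the variance. The contigs are not independent replicates, so these correlations describe the libraries and carry no test. The spread between replicates was wide, with a biological coefficient of variation of 73.7% over contigs and 54.5% over clusters. No pair of replicates agreed within sampling noise, as the chi-square statistic per degree of freedom between 2 replicates was 29.6 to 59.8, and each library was counted as 1 sample.

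**Figure D1:**
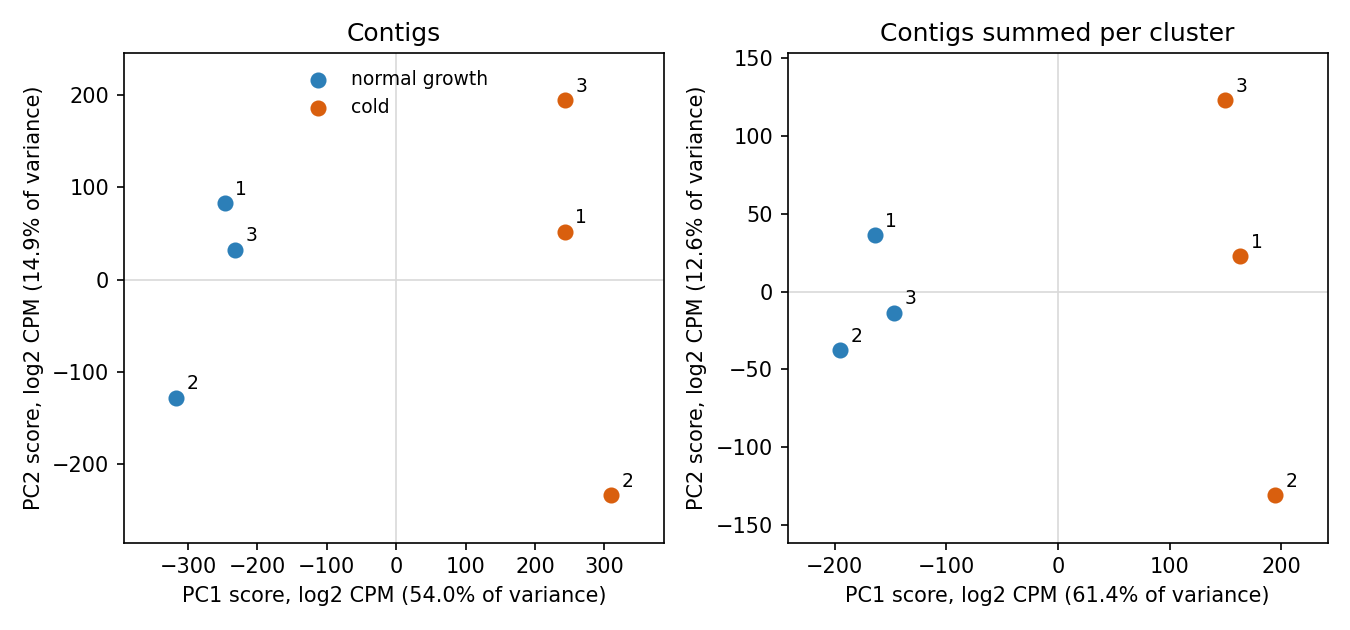
Principal component scores of the 6 libraries from log2 CPM, for contigs (left) and for counts summed per cluster (right); each point is 1 library, numbered by replicate, and the axes give the share of variance in percent. The first component, with 54.0% of the variance for contigs and 61.4% for clusters, parts the 3 cold libraries from the 3 normal growth libraries.

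The second comparison asked how many contigs were in use in each group and how evenly the reads were spread over them. Cold seedlings showed reads on more contigs. With every library thinned to 15284111 reads, 123844 ± 6740 contigs (SD, n = 3) had at least 1 read in the cold and 103134 ± 5636 (SD, n = 3) in normal growth. All 3 cold libraries lay above all 3 normal growth libraries (exact permutation test, two-sided, p = 0.1, the smallest p that 3 libraries against 3 allow). Clusters and unclustered contigs with reads went the same way, at 77903 ± 6037 (SD, n = 3) in the cold and 62519 ± 3969 (SD, n = 3) in normal growth. Reads were less concentrated in the cold: the 50 most abundant contigs of a library took 9.78% ± 0.234 of its reads (SD, n = 3), against 13.1% ± 0.294 in normal growth (SD, n = 3; exact permutation test, two-sided, p = 0.1). A large part of this lay in 1 contig, the most abundant in all 3 normal growth libraries. It took 2.44% ± 0.112 of the reads in normal growth and 0.948% ± 0.142 in the cold (SD, n = 3 each).

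**Figure D2:**
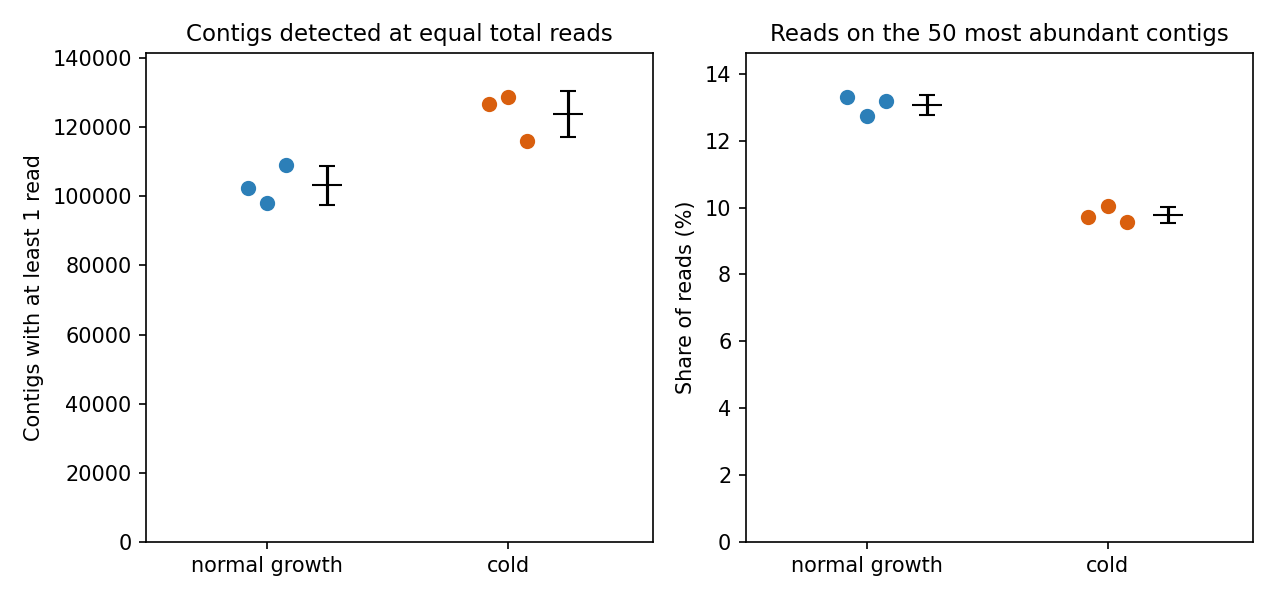
Contigs with at least 1 read at an equal total of reads per library (left), and share of reads on the 50 most abundant contigs of each library, in percent (right). Points are libraries and bars are the mean ± SD of 3 libraries; the cold libraries lie between 116130 and 128595 contigs, above the normal growth range of 97915 to 109111, and below normal growth in the share.

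A set of contigs was seen in 1 group alone. In the cold, 1398 contigs had at least 10 reads in each of the 3 libraries and were listed at 0 in all 3 normal growth libraries. The reverse held for 290 contigs. The total of 1688 depended on the read minimum, and was 2764 at 5 reads and 913 at 20 reads. The cold-only contigs took 0.680% ± 0.155 of the cold reads (SD, n = 3) and the normal-growth-only contigs 0.141% ± 0.0325 of the normal growth reads (SD, n = 3). For counts summed per cluster the numbers were 384 and 61. No other division of the 6 libraries into 3 and 3 gave more than 112 such contigs or 29 such clusters. The other divisions mix cold and normal growth libraries in each group, so these numbers are no clean measure of chance. A 0 allows up to 3 reads of a library, or 0.166 to 0.196 CPM, for counting error only, and shared reads that were assigned to a sister contig also leave a 0.

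The third comparison, and the main one of the design, tested each contig between cold and normal growth. Contigs changed in both directions, and with all 6 libraries more of them rose. Of the 70729 contigs with enough reads to test, 6888 were higher and 4617 lower in the cold at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Nearly all, 6859 higher and 4583 lower, changed at least 2-fold. The contig test had little power for small changes. In simulated data it recovered none of 200 contigs changed 4-fold. The 2-fold share and the medians below therefore describe what it could call, not the sizes of all changes. The median log2 fold change was 3.99 among the contigs that rose and -2.80 among those that fell. Of the rising contigs, 1501 had no read in any normal growth library after rounding, and 286 of the falling contigs had none in the cold. With these set at their lower bound against 3 reads over the empty group, the medians were 3.91 and -2.80, and 3334 contigs rose and 1057 fell at least 16-fold. All 11505 called contigs had 3 cold libraries on 1 side of the 3 normal growth libraries, which a call here nearly requires. Among all tested contigs 44.9% were parted in this way, where chance gives 10%.

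The rising contigs were chosen on these same libraries, and together they went from 3.69% ± 0.0135 of the reads in normal growth to 22.05% ± 0.322 in the cold (SD, n = 3 each). The falling contigs went from 27.4% ± 1.12 to 7.18% ± 0.382 (SD, n = 3 each). The balance of directions varied with abundance. Below a mean of 1 CPM over all libraries, 1344 of 9650 tested contigs rose and 288 fell. Between 1 and 10 CPM 3840 of 43883 rose and 2085 fell. Between 10 and 100 CPM 1462 of 15790 rose and 1962 fell, and above 100 CPM 242 of 1406 rose and 282 fell. The filter asks for about 10 reads in as many libraries as a group holds, so a contig of low mean can be tested through 1 group alone. How far this set the balance in the lowest class was not tested. With library size alone as the scaling, the majority in the class above 100 CPM turned, to 275 higher and 238 lower, and the class from 10 to 100 CPM was near balance with 1694 higher and 1730 lower. Of the unclustered contigs tested, 17.9% of 22884 were called, and of the clustered ones 15.5% of 47845. The median length was 1933 bases for the contigs that rose, 1752 for those that fell and 1761 for the tested contigs that were not called.

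The number of called contigs fell when any 1 library was left out. It was 142 without normal growth replicate 1, 2172 without normal growth replicate 2 and 653 without normal growth replicate 3. It was 174 without cold replicate 1, 3199 without cold replicate 2 and 1775 without cold replicate 3. At an unadjusted p under 0.05 (edgeR) these fits held 21857 to 25367 contigs, against 24239 with all 6 libraries. They had fewer residual degrees of freedom and tested 76992 to 81093 contigs, against 70729. The lower counts therefore do not show that 1 library carried the changes. More contigs rose than fell in each of these fits except that without normal growth replicate 3, where 318 rose and 335 fell. The majority was small, with 72 higher and 70 lower without normal growth replicate 1, and 91 and 83 without cold replicate 1. Over the 6 fits 48.7% to 55.3% of the calls were higher, against 59.9% with all libraries. The number of called contigs also moved with the test and the contigs tested together. It was 23288 of 99844 contigs with the DESeq2 Wald test and 18345 of 91452 with limma-trend on log2(FPKM + 0.1). With limma-voom, on 70729 contigs as in the main test, it was 14598. At an adjusted p under 0.01, 267 contigs remained, 139 higher and 128 lower, and the smallest adjusted p of any contig was 0.0023 (edgeR).

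**Figure D3:**
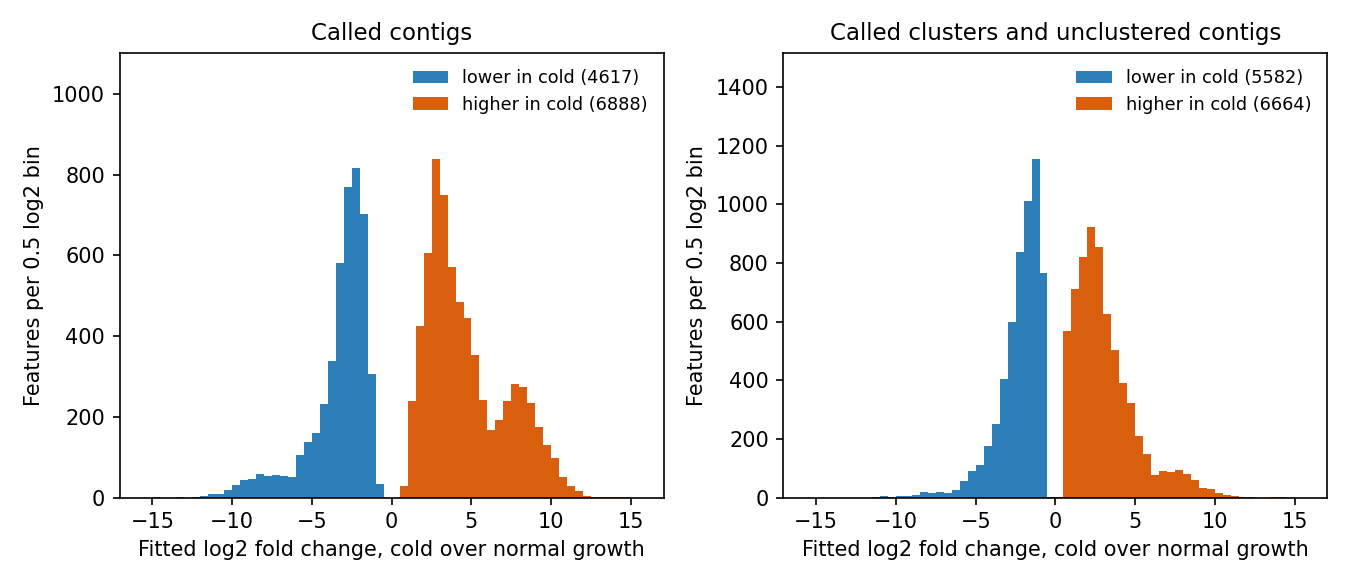
Fitted log2 fold changes of the called contigs (left) and of the called clusters and unclustered contigs (right), cold over normal growth, as numbers of features per 0.5 log2 bin. The left panel shows 6888 contigs higher and 4617 lower in the cold; the bulge of rising contigs at the far right lies where contigs with no read in normal growth fall, whose fitted folds are not bounded by the data.

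Counts summed over the contigs of each cluster, which do not depend on how reads were divided within a cluster, were tested in the same way. This level was one of the alternatives fixed before the data were examined, and is given as a result of its own because of what both levels showed. Of 35987 clusters and unclustered contigs tested, 6664 were higher and 5582 lower in the cold at an adjusted p under 0.05 (edgeR). The called share was 34.0%, against 16.3% of contigs. Only 4278 of the 12246 called features were clusters with at least 2 tested contigs, and unclustered contigs have the same counts at both levels. The 2 fits also differed in their dispersions and in the features adjusted over, so the shares do not isolate the effect of summing. Of the called features, 6093 rose and 4816 fell at least 2-fold. The median log2 fold change was 2.67 for those that rose and -1.91 for those that fell, and 41.1% of them changed less than 4-fold. With features empty in 1 group set at their lower bound, 1609 rose and 556 fell at least 16-fold. The called share was 49.1% of the 1961 features above a mean of 100 CPM and 30.5% of the 5410 below 1 CPM. Leaving out 1 library gave between 6997 and 12211 calls, with the lowest values without normal growth replicate 1 (6997) and without cold replicate 1 (7794), and more features rose than fell in each of these fits.

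**Figure D4:**
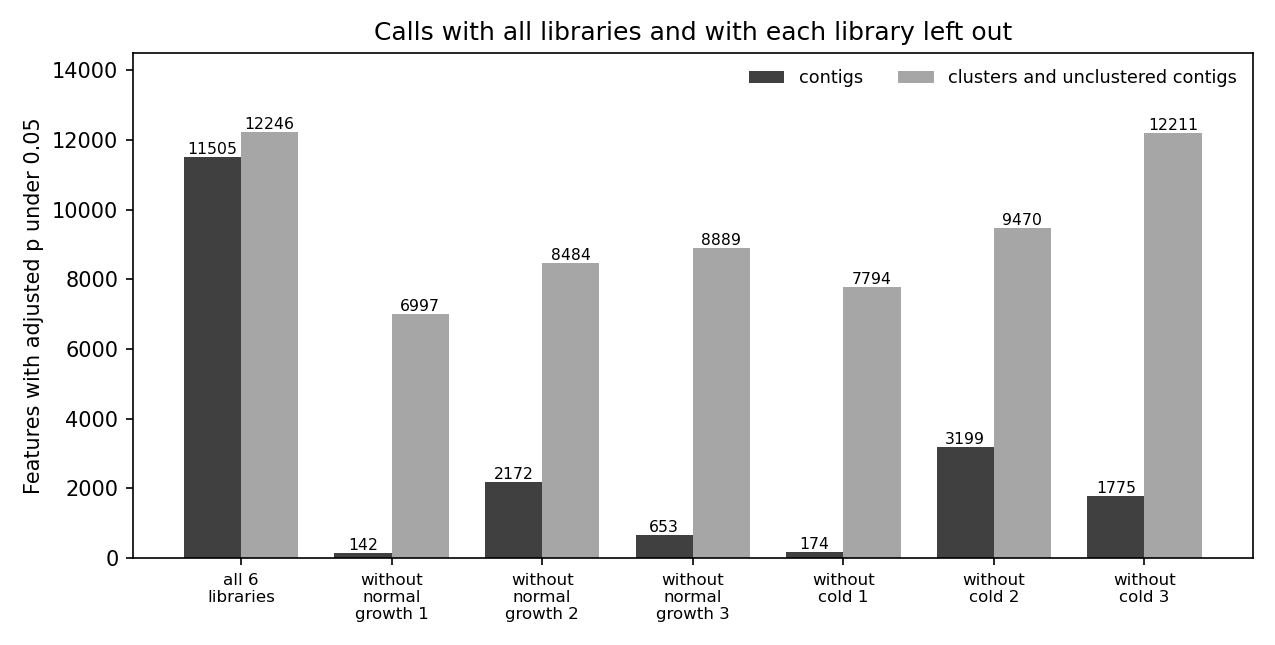
Number of features with an adjusted p under 0.05 (edgeR) with all 6 libraries and with each library left out, for contigs (dark bars) and for clusters and unclustered contigs (light bars). Contig calls fell from 11505 to between 142 and 3199, and cluster calls from 12246 to between 6997 and 12211.

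The rising contigs with the largest fitted log2 fold change were CL4344.Contig3_All, of 2343 bases, and CL6395.Contig5_All, of 2539 bases. Fitted folds against a group at 0 depend on the prior count, and with such groups set at 3 reads 3 other called contigs with a mean of at least 2 CPM rose more than CL4344.Contig3_All. Both were listed at 0 reads in all 3 normal growth libraries. CL4344.Contig3_All had 2459, 7052 and 1992 estimated reads in cold replicates 1, 2 and 3, or 229 ± 163 CPM (SD, n = 3), at least 3886-fold higher than 3 reads over the normal growth group (adjusted p = 0.011, edgeR). CL6395.Contig5_All had 2829, 5490 and 91.9 reads, or 170 ± 160 CPM (SD, n = 3), at least 2874-fold higher (adjusted p = 0.029, edgeR). These bounds set the mean of the cold group against 3 reads and leave out the spread between cold libraries. The clusters that hold both contigs changed far less. The 4 contigs of CL4344 together went from 907 ± 43.3 CPM in normal growth to 2337 ± 1153 CPM in the cold (SD, n = 3 each), a log2 fold change of 1.37 ± 0.34 (SE; adjusted p = 0.022, edgeR). The 8 contigs of CL6395 went from 408 ± 85.8 to 1411 ± 228 CPM (SD, n = 3 each), a log2 fold change of 1.79 ± 0.23 (SE; adjusted p = 0.0031, edgeR).

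The falling contigs with the largest fitted log2 fold change, CL15882.Contig1_All of 2191 bases and CL15882.Contig6_All of 3060 bases, belonged to 1 cluster and were listed at 0 in all 3 cold libraries. With groups at 0 set at 3 reads, 2 called contigs, CL15882.Contig1_All among them, fell more than CL15882.Contig6_All. CL15882.Contig1_All had 1339, 276 and 7454 estimated reads in normal growth replicates 1, 2 and 3, or 176 ± 224 CPM (SD, n = 3), and was at least 2934-fold lower in the cold (adjusted p = 0.024, edgeR). CL15882.Contig6_All had 287, 196 and 3425 reads, or 75.9 ± 107 CPM (SD, n = 3), and was at least 1262-fold lower (adjusted p = 0.029, edgeR). The 8 contigs of CL15882 together went from 990 ± 827 to 25.2 ± 16 CPM (SD, n = 3 each), a log2 fold change of -5.30 ± 0.81 (SE; adjusted p = 0.0054, edgeR). Each of these 4 contig calls was lost in at least 2 of the 6 fits that left out a library, with adjusted p (edgeR) of 0.022 to 0.055 for CL4344.Contig3_All, 0.036 to 0.084 for CL6395.Contig5_All, 0.044 to 0.076 for CL15882.Contig1_All and 0.051 to 0.077 for CL15882.Contig6_All. The lower bounds of the fold set a group mean against 3 reads, leave out the spread between libraries, and also rested on single libraries. Without cold replicate 2 they were 2303 for CL4344.Contig3_All and 1566 for CL6395.Contig5_All, and without normal growth replicate 3 they were 801 for CL15882.Contig1_All and 239 for CL15882.Contig6_All. Over the 6 leave-outs they ranged from 2303 to 4848, 1566 to 4266, 801 to 4266 and 239 to 1797 in that order. Leaving out a library of the group at 0 also lowers a bound, because the 3 reads are then set against fewer reads.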

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

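The unrounded counts, the cluster and leave-one-out settings for separation, and the settings for clusters as a result of their own, detection, concentration, contigs seen in 1 group and the bounds of the named contigs were chosen after seeing the data. The 11505 contig calls (11442 at least 2-fold) moved by over 1.5 times under the DESeq2 Wald test (23288 and 23286, of which 11296 and 11293 were shared), under limma-trend on log2(FPKM + 0.1) (18345 and 18216), at an adjusted p under 0.01 (267) and on leaving out 1 library (142 to 3199 and 142 to 3198). The other scalings, filters, limma-voom, log2(FPKM + 1), summing per cluster and unrounded counts stayed within 1.5 times, with more contigs higher than lower in each. Deviations from the group means of same-numbered libraries correlated at -0.089, -0.0068 and -0.077 over contigs and 0 of the 6 libraries correlated best with its own number, so the numbers did not pair the samples. With the replicate block edgeR called 0 contigs (18452 at an unadjusted p under 0.05) and 6319 clusters, which differs from the 12246 without it by over 1.5 times; the block leaves fewer residual degrees of freedom. Cluster calls were 6997 to 12211 on leaving out 1 library and within 1.5 times under all other settings run. Library size alone moved the median log2 fold change of all contigs from 0.12 to 0.23 and the share of higher calls from 59.9% to 64.5%. Within-group correlations exceeded those between groups by 0.26 on average, by 0.20 on log2(FPKM + 1) and by 0.18 for clusters. The excess of 20710 contigs detected in the cold was 13722 at a minimum of 5 reads, and the difference of -3.30 percentage points in reads on the 50 most abundant contigs was -3.66 in TPM. The 1688 contigs seen in 1 group alone were 2764 at 5 reads, 913 at 20 reads and 2364 to 2754 on leaving out 1 library, which can only raise this number because fewer libraries have to meet the rule. Of the counts, more contigs or clusters rose than fell in each setting run except without normal growth replicate 3 (318 contigs higher, 335 lower) and the replicate block for contigs. On leaving out 1 library the share of higher contig calls was 48.7% to 55.3%, against 59.9% in the main test. The DESeq2 Wald test gave no adjusted p for CL15882.Contig6_All. Where no cause is named, the cause was not tested. The planned tests of gene lists and functional terms were not run, since contigs have no names here. Depth limits the contigs at 0, which allow up to 0.196 CPM in the shallowest library.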

Other observations

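The tests of sequencing depth and of RNA of 1 other organism were chosen after values bearing on them were seen. Contigs of 1 cluster mostly moved together. Of 1578 clusters with at least 2 called contigs, 418 held both a rising and a falling one, fewer than the 873 to 974 found when directions were permuted over the same contigs 100 times. In 214 of these 418 clusters the summed count was called as well. Of the 11505 called contigs, 2157 lay in clusters whose total was not called. The remaining 9348 included all 4101 called unclustered contigs, which have the same counts at both levels. Only contigs in clusters could go against their total, and 382 of the 9348 did. In turn, 4829 of the 12246 called clusters and unclustered contigs held no called contig. Unclustered contigs among these had the same counts in both fits.

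The wider detection in the cold libraries is the first pattern to look at again. A difference in sequencing depth is argued against, since each of the 3 cold libraries was shallower than each normal growth library and yet 19730 more contigs on average had a read before thinning, and so are a few abundant contigs taking the counts, since 97.4% of the difference stayed without the 117 contigs among the 50 most abundant of any library. A spread of reads over more contigs of the same clusters is argued against as the whole cause, since 15384 more clusters and unclustered contigs were detected in the cold. RNA of 1 other organism stays open: over 2943 contigs with no read in normal growth and at least 50 in the cold the robust SD of the log2 ratio between 2 cold libraries was at least 1.75, but contigs with reads in both groups, matched on cold reads, also varied by 1.27 to 1.596, so a wide spread excludes nothing. Several organisms, unspliced RNA or genomic DNA, and a broader set of transcripts in cold or older seedlings stay open as untested.

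Opposite changes within a cluster are the second pattern. Over 7902 clusters thinned to 100 reads in every library, 23.1% of a cluster's reads on average sat on different contigs in 2 libraries of 1 group, against 7.26% when 1 library was drawn again. Redrawing took reads without replacement from the same counts, in clusters with as few as 100 reads. The 7.26% therefore understates the sampling noise between independent libraries. Between groups the mean was 29.4%, or 1.28 times that within groups, and the ranges overlapped, at 17.8% to 27.9% within and 25.3% to 35.4% between groups. The real split gave an excess between groups of 6.37 percentage points and the highest other split -0.17, so 1 of the 10 splits reached it, and 10 splits are too few for a share under 0.05. The other splits mix both treatments in each group, so an excess in the real split lowers theirs. A division of reads or a difference between plants that does not follow the treatment cannot be told apart from contig use that does, because the ranges overlap and the splits are few.

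For the main comparison, the real split called 11505 contigs, 11442 contigs at least 2-fold changed and 12246 clusters and unclustered contigs, and the highest of the other 9 splits called 0 in each case (edgeR), with at most 1467 contigs and 1041 clusters at an unadjusted p under 0.05. Each of the other splits mixes both treatments in each group, so a treatment difference widens the spread within groups and makes calls unlikely. Only 1 split, the real one, reached each count, and 10 splits are too few for a share under 0.05.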
